A study of Homo sapiens with 4 samples.

How the data were processed

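MDA-MB-231, an established human breast carcinoma line that lacks estrogen and progesterone receptors and HER2 amplification, was grown for 3 days in 1 of 2 media. Both media were made from concentrated DMEM diluted with 9 parts of a hypotonic saline. For treated medium the saline had first been exposed for 30 minutes to the dc DEP EMF of a BEFE (Bio-Electric Field Enhancement) unit, and for control medium it had not. Total RNA was extracted on columns, amplified and labelled with whole-transcript kits and hybridised to an Affymetrix human array, per the labels' protocols.

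The series held 4 samples in 4 groups of 1: control and treated medium, each at gene level and at exon level. The 5391 probe sets found in both the gene-level and the exon-level table had identical values in each medium. The gene-level and exon-level columns were therefore taken as 2 summaries of the same hybridisation and never as replicates. The labels name 5 biological replicates per group in the RNA quality check. The files used here hold 1 column of values per medium and level, and the labels do not say whether that column is 1 array, pooled RNA or an average. No standard error or p-value could be computed, and no test was run between the media.

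The deposited gene-level table (53617 probe sets) and exon-level table (352859 probe sets) hold log2 signal, normalized with RMA in Affymetrix Expression Console, per the submitters' processing notes. Versions were not given in the sources used here. RMA subtracts background, forces the arrays to 1 distribution of probe signals and summarises probes, so a shift shared by most genes is not visible in these values. The authors' deposited comparison sheet holds an intensity per medium on a linear scale, a control over treated ratio, and gene symbols and accessions for the gene-level probe sets. Its intensities equalled the antilog of the deposited gene-level log2 values, with gaps of at most 5.03e-05 on the log2 scale. Lists of probe sets with a ratio of at least 2 in either direction were deposited by the authors in the same table. No genome build was named in the files, so no coordinates are given.

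Gene names came from that sheet. Of the 53617 gene-level probe sets, 25937 had 1 symbol, 3221 had several names and 24459 had no symbol. Names were not taken from probe sets with several. The 25937 probe sets gave 24305 distinct symbols, and 906 symbols with more than 1 transcript cluster were represented by the cluster with the highest mean signal. Current symbols were looked up in a RefSeq table of assembly GRCh38.p14, which matched 23315 symbols (18054 by accession, 4586 by symbol and 675 by an older symbol). The other 990 kept the name in the file.

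Differences were log2 treated minus log2 control. Genes counted as measured when their mean over both media reached a floor of 7.17, the median of that mean over probe sets with 1 symbol, which left 12353 genes. A gene was counted as higher or lower at a difference of at least 2-fold. For exon-level probe sets the same rule gave a floor of 7.34 and 176432 probe sets. For arrays, the number of hybridisations limits the precision, and here no spread between cultures could be measured.

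For 38 gene lists, the median difference of the members above the floor was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. A list stood apart when its percentile was below 2.5 or above 97.5. The 4 lists with fewer than 5 members above the floor were given no percentile. About 1.7 of the other 34 lists would stand apart by chance. Genes of a list are often regulated together, so the percentile describes these columns of values and is no test of the media. The random draws were reseeded after the first results had been seen, so that each list's draw no longer depended on the other lists. That moved the common reference genes, which lie close to the limit, from standing apart to not standing apart, and a second set of draws is given in the closing section.

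The lists covered voltage-gated calcium channel subunits, calcium stores and pumps, potassium channels, sodium channels with the sodium-potassium pump, TRP and Piezo channels, chloride and volume-regulated channels, aquaporins and gap junction proteins. They also covered osmotic stress, heat shock, endoplasmic reticulum stress, ATF4 targets, oxidative stress, metallothioneins, cell cycle, replication-dependent histones, p53 targets, apoptosis, interferon-stimulated genes, inflammatory genes, hypoxia with glycolysis, sterol synthesis and fatty acid synthesis. The remaining lists were mesenchymal, epithelial and basal breast genes, integrins, actin and migration, matrix proteases, immediate early genes, cytosolic ribosomal proteins, oxidative phosphorylation, autophagy with lysosome, DNA repair, leukocyte, endothelial and blood, and fibroblast markers, and common reference genes. The 38 lists, the floor, the thresholds and the rule for named genes were fixed before the data were examined. A further 9 lists were chosen after seeing the data and appear only in the closing section. They were cytosolic and mitochondrial aminoacyl-tRNA synthetases, amino acid transporters, endoplasmic reticulum chaperones, G1 to S phase genes, and G2 phase and mitosis genes. The others were EGF family ligands, and replication genes and mitosis genes outside the cell cycle list.

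Named genes were the 12 highest and the 12 lowest differences above the floor among genes with 1 symbol. Small RNA genes, uncharacterised loci, ribosomal RNA and olfactory receptor genes were left out. Where a gene had 3 or more exon-level probe sets, their median also had to show the same sign, which left out 0 genes. To these were added the 4 members with the largest absolute difference in each list that stood apart. The last part of the rule added the 2 such members of each channel, aquaporin, gap junction, osmotic stress, cell cycle and migration list. Ties went to the gene first in the alphabet. Some genes that the rule or a count would name are not reported here. Other genes are named only to complete a count or a group, and were chosen after their values were seen.

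No table used here assigns exon-level probe sets to genes. Probe sets were assigned to the transcript cluster whose identifier interval held theirs, an inferred rule checked on the values. Across 26802 clusters with at least 3 such probe sets, the correlation of signal levels was 0.982 with the cluster's own interval and 0.205 and 0.203 with the neighbouring intervals.

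Alternatives were quantile normalization, median centring, removal of the trend of the difference on mean level (lowess span 0.3), no floor, a floor at the 75th percentile, thresholds of 1.5-fold and 3-fold, the mean over the clusters of a symbol, the median over exon-level probe sets, and leaving out the largest member of a list. Leaving out genes of the ATF4 list, the identifier intervals and a second set of random lists were added after seeing the data. The calculations were tested on simulated data with noise of SD 0.380 on 12353 genes for treated against control at gene level. Of 100 genes set to a 4-fold difference, 100% passed the 2-fold threshold, and of 100 genes set to 2.5-fold, 77% did. In the same simulation 91 of 12121 unchanged genes passed 2-fold. The 1 list shifted by 0.5 lay at percentile 100, and 0 of the 33 other lists stood apart. The simulated noise was independent between genes and had the same SD at every signal level. That SD was below the SD of the measured differences (0.543), and fewer random lists were drawn than for the data. The simulation checks the calculations and gives no error rate for the real genes or lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.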

Results

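Gene expression was measured in MDA-MB-231 cells grown for 3 days in treated or control medium, with 1 column of gene-level and 1 column of exon-level log2 signal per medium. Median gene-level signal was 6.33 in control and 6.31 in treated medium. Each difference below is treated minus control, has no replicate check and carries no error or p-value. The comparison addresses which genes differ in expression when cells grow in medium whose saline had been exposed to the field.

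In treated medium, genes of the amino acid and integrated stress response were higher and genes of DNA replication and mitosis were lower. PTGS2, the inducible prostaglandin synthase, had the highest difference, with a log2 signal of 7.98 in control and 12.68 in treated medium, a fold of 25.9 (transcript cluster 16697370). CTH, an enzyme of cysteine synthesis, had a log2 signal of 7.21 in control and 11.53 in treated medium, and CHAC1, which degrades glutathione, of 7.70 and 11.70. FAM111B had the lowest difference among genes with 1 symbol above the floor that the naming rule covers, with a log2 signal of 10.96 in control and 7.05 in treated medium, a difference of -3.90 (transcript cluster 16725041). CCNE2, the cyclin E2 gene that acts at entry into S phase, was 9.89-fold lower, and TYMS, the thymidylate synthase gene, was 6.76-fold lower.

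Of the 12353 genes above the floor, 398 were at least 2-fold higher in treated medium and 428 were at least 2-fold lower, together 6.69% of genes. The log2 differences had an SD of 0.543 and quartiles of -0.26 and 0.25, and 80.8% of genes lay within 1.5-fold. Across genes, signal in the 2 media had a Pearson r of 0.924, where genes are not independent replicates. As a gauge of genes that this line is not known to use, 392 olfactory receptor genes, chosen after seeing the data, had an SD of 0.346 at a median signal of 4.81. Of the 392 genes, 6 (1.53%) differed by at least 2-fold, but only 15 were above the floor. Their spread therefore gives no error rate for the 12353 genes above it.

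**Figure D1:**
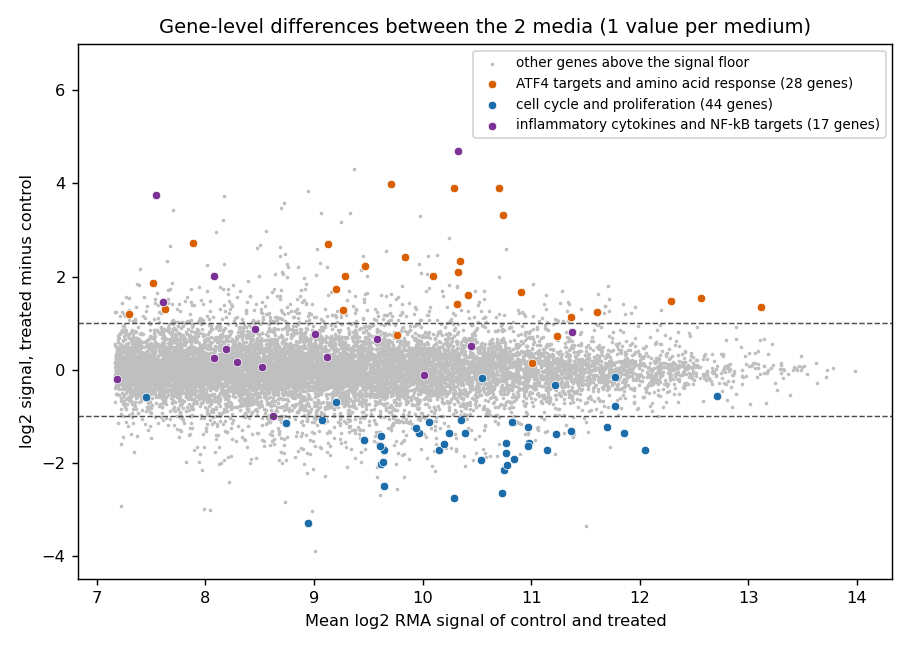
Each point is 1 gene above the floor, with the mean log2 RMA signal of both media on the x axis and log2 treated minus control on the y axis; dashed lines mark 2-fold, and colours mark the ATF4, cell cycle and inflammatory lists. All 28 genes of the ATF4 list lie above 0 and all 44 genes of the cell cycle list lie below 0.

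The other genes with the highest differences included stress, cytokine and amino acid genes. GDF15, a stress-induced secreted factor, and SESN2, which restrains mTORC1 when leucine is short, were each 14.9-fold higher. TNFRSF9, a costimulatory receptor of the TNF receptor family, was 14.2-fold higher, and IL1A, the interleukin-1 alpha gene, had a log2 signal of 5.67 in control and 9.41 in treated medium. TCP11L2 had a difference of 3.59. JHDM1D (current symbol KDM7A), a histone demethylase gene, had signals of 6.96 in control and 10.43 in treated medium, and ALDH1L2, a mitochondrial folate enzyme gene, had signals of 5.99 and 9.42. SLC6A9, a glycine transporter gene, was 10.4-fold higher, and ERN1, which encodes the endoplasmic reticulum stress sensor IRE1, was 10.2-fold higher. The floor applies to the mean of both media, and the control signals of TNFRSF9, IL1A, TCP11L2, JHDM1D and ALDH1L2 were under 7.17. Set against the floor in place of the control signal, IL1A was 4.74-fold, ALDH1L2 4.77-fold and JHDM1D 9.59-fold higher, and the place of these 3 among the highest genes is uncertain.

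Among the lowest differences were further replication, mitosis and histone genes. CDCA7 was 7.20-fold lower, FAM64A (current symbol PIMREG) 6.44-fold, and KIF20A, a kinesin of cytokinesis, 6.30-fold. SDPR (current symbol CAVIN2), which encodes a caveola protein, was 5.93-fold lower, and GINS2, part of the replicative helicase, was 5.67-fold lower. The histone genes HIST1H2BM and HIST1H2BB were 10.4-fold and 8.25-fold lower. HIST1H2AI and HIST1H3J had treated signals of 6.49 and 5.75, under the floor of 7.17, and their control signals were 5.00-fold and 2.85-fold above that floor. The treated signal of FAM111B was also under it. Histone genes have near-identical copies, so the signal of a single one of them is uncertain.

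**Figure D2:**
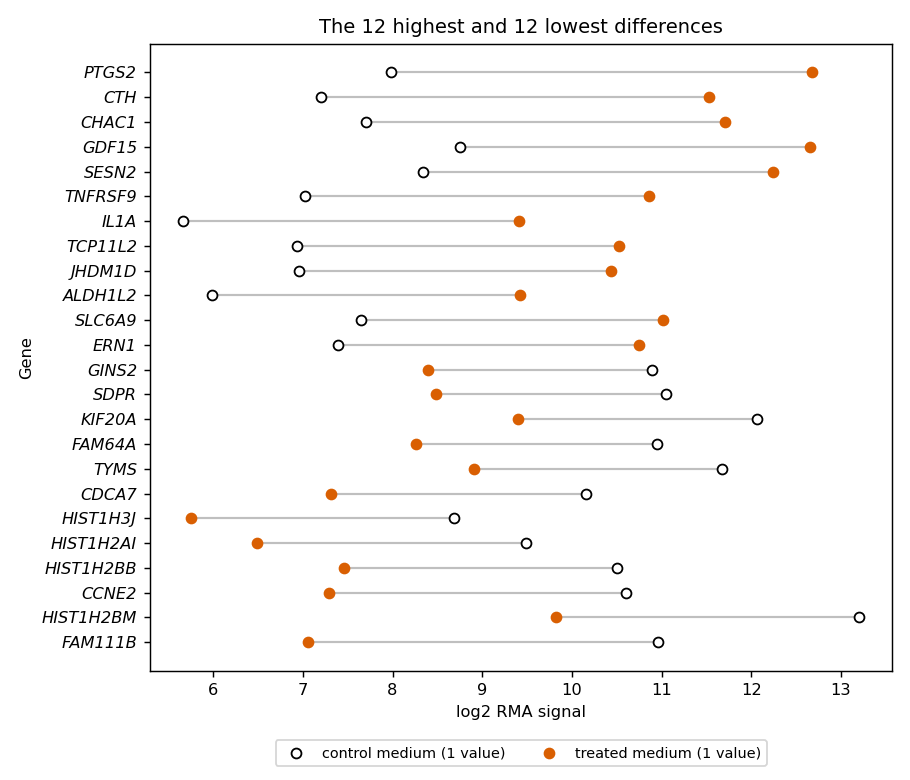
Log2 RMA signal (x axis) of the 12 genes with the highest and the 12 with the lowest difference (y axis), with an open point for control and a filled point for treated medium, 1 value each. PTGS2 runs from 7.98 to 12.68 and FAM111B from 10.96 to 7.05.

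The list of ATF4 targets, genes of the amino acid response and the integrated stress response, stood furthest above the random lists. Its median difference was 1.71 (quartiles 1.30 and 2.36), at percentile 100, where 95% of the random lists lay between -0.18 and 0.16. All 28 members were above 0 and 25 were at least 2-fold higher. After CHAC1, GDF15 and SESN2, DDIT4, an inhibitor of mTORC1 signalling, was 10.0-fold higher. The transcription factor gene DDIT3 had a difference of 2.71, the asparagine synthetase gene ASNS 2.70 and the serine synthesis gene PSAT1 1.54. ATF4 itself, whose protein is controlled largely at translation, had a difference of 0.72. DDIT3, ASNS, PSAT1 and ATF4 were picked after their values were seen.

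The cell cycle list stood furthest below the random lists. Its median difference was -1.41 (quartiles -1.75 and -1.13), at percentile 0. All 44 members were below 0 and 37 were at least 2-fold lower. CCNE2, TYMS, KIF20A and GINS2 were the lowest. The proliferation marker gene MKI67 had a difference of -1.92, the replication clamp gene PCNA -2.05 and the G2 cyclin gene CCNB1 -1.74, and all 3 were picked after their values were seen. CCND1, the cyclin D1 gene, was nearest to 0 in the list, at -0.16.

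The medians of replication-dependent histone genes and DNA repair genes were also lower. The histone list had a median of -0.87 at percentile 0. Of its 18 members, 8 were at least 2-fold lower and 0 at least 2-fold higher. With exon-level medians it was -0.50, but only over members with at least 3 exon-level probe sets. That left out HIST1H2BM, HIST1H2BB, HIST1H2AI and HIST1H3J, so the 2 medians are not of the same genes. The DNA repair list had a median of -0.72 at percentile 0, with 12 of 38 members at least 2-fold lower. RAD54L, a recombination gene, was 4.09-fold lower, the DNA ligase gene LIG1 3.40-fold, the Fanconi anemia gene FANCA 3.10-fold and the helicase gene BLM 2.58-fold. XRCC3, another recombination gene, picked to complete the count, was the 1 member at least 2-fold higher, with a difference of 1.22. The treated signal of RAD54L was under the floor.

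The medians of inflammatory genes and metallothioneins were higher. The inflammatory list had a median of 0.52 at percentile 99.99 (0.17 without a floor), with 4 of 17 members at least 2-fold higher. Those were PTGS2, IL1A, IL8 (current symbol CXCL8), a neutrophil chemokine gene with signals of 7.08 in control and 9.08 in treated medium, and the adhesion molecule gene ICAM1 at 2.75-fold. The control signals of IL1A, IL8 and ICAM1 were under the floor. CCL2, a monocyte chemokine gene picked to complete the count, was the 1 member at least 2-fold lower. Among 6 metallothionein and zinc genes the median was 0.74 at percentile 99.97 (0.37 without a floor). The zinc exporter gene SLC30A1 was 2.41-fold higher and MT1F 2.30-fold higher, MT1X had a difference of 0.92, and MT1A was 2.25-fold lower. Metallothionein genes are near-identical copies, and their single values are uncertain.

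The NRF2 target, endoplasmic reticulum stress and p53 target lists stood apart by smaller medians, and a minority of their members passed 2-fold. Of 25 NRF2 targets, with a median of 0.22 at percentile 99.5, 5 were at least 2-fold higher. HMOX1, the inducible heme oxygenase gene, was 9.89-fold higher, the ferritin heavy chain gene FTH1 3.37-fold, the malic enzyme gene ME1 3.05-fold and the cystine transporter gene SLC7A11 2.77-fold. TXNRD1, at 1.40, was the other. With a floor at the 75th percentile the NRF2 list no longer stood apart (median 0.15). Of 22 endoplasmic reticulum stress genes, with a median of 0.18 at percentile 98.7, 5 were at least 2-fold higher. They were ERN1, DNAJB9 (4.03-fold), HERPUD1 (3.08-fold), XBP1 (2.41-fold) and SEL1L, at a difference of 1.21. This list no longer stood apart without ERN1, its largest member, without a floor or with exon-level medians (median 0.11 each time). Of 22 p53 targets, with a median of 0.20 at percentile 98.7, 3 were at least 2-fold higher. These were SESN2, GADD45A (4.14-fold) and TP53INP1, and TNFRSF10B, a death receptor gene, was 1.79-fold higher. The control signal of TP53INP1 was under the floor, against which it was 1.86-fold higher, less than 2-fold. The p53 list no longer stood apart with a floor at the 75th percentile (median 0.20) or with exon-level medians (0.17). TXNRD1 and SEL1L were named to complete counts.

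Hypoxia, immediate early, integrin and osmotic stress lists were also above the random lists. The hypoxia and glycolysis list had a median of 0.19 at percentile 99.8, and 5 of 38 members were at least 2-fold higher. The angiogenic factor gene VEGFA was 4.06-fold higher, the collagen cross-linking enzyme gene LOX 3.24-fold, ANGPTL4 3.10-fold and NDRG1 2.65-fold, and HK2, named to complete the count, had a difference of 1.38. VEGFA also belongs to the ATF4 list. The immediate early list had a median of 0.23 at percentile 99.9, and 5 of 27 members were at least 2-fold higher. NR4A2 was 2.45-fold higher, JUNB 2.27-fold and JUND 2.22-fold, and KLF4, named to complete the count, had a difference of 1.13. The other was ATF3, whose control signal was under the floor, against which it was 1.65-fold higher, less than 2-fold.

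For 28 integrin and focal adhesion genes the median was 0.24 at percentile 99.9, but without a floor it was 0.045 and the list did not stand apart. ITGA5, the fibronectin receptor subunit gene, was 2.40-fold higher and ITGB3 was 2.05-fold lower. ITGA3, a laminin receptor subunit gene, was 1.61-fold higher. Of 12 osmotic stress genes, with a median of 0.25 at percentile 98.2, NFAT5, the transcription factor gene of the hypertonic response, was 2.04-fold higher and HSPA4L 2.55-fold lower. AKR1B1, which makes sorbitol, was 1.84-fold higher and the kinase gene WNK4 1.66-fold higher. With the exon-level median, the difference of NFAT5 was 0.94, under 2-fold. The control signal of WNK4 was under the floor, and with a floor at the 75th percentile the osmotic list no longer stood apart (median 0.28).

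The medians of the heat shock, oxidative phosphorylation and interferon lists were below the random lists. The heat shock list had a median of -0.31 at percentile 0.1, with 4 of 21 members at least 2-fold lower: HSPA4L, HSPA1B (2.54-fold), HSPA1A (2.29-fold) and DNAJA1 (2.02-fold). HSPA1A and HSPA1B are near-identical copies whose signals are uncertain. DNAJA1 lay just under 2-fold under each of the 3 other scalings. The oxidative phosphorylation list had a median of -0.25 at percentile 0.05, with 43 of 45 members below 0 and 0 past 2-fold. ATP5G3 (current symbol ATP5MC3) was 1.96-fold, NDUFB6 and ATP5G1 (current symbol ATP5MC1) each 1.76-fold and UQCRB 1.66-fold lower, and ATP5G3 passed 2-fold with the exon-level median (-1.06). The interferon list had a median of -0.27 at percentile 0.24, with 1 of 26 members at least 2-fold lower. That member, OAS3, an antiviral RNA sensor gene, was 4.04-fold lower, and USP18, HERC6 and IFI44 were 1.96-fold, 1.93-fold and 1.80-fold lower. Treated signals of OAS3 and IFI44 were under the floor. The interferon list no longer stood apart without OAS3 or with a floor at the 75th percentile (median -0.14 each time).

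The medians of mesenchymal and fatty acid genes lay just below the random lists, and neither list stood apart with a floor at the 75th percentile (-0.11 and -0.17) or with exon-level medians (-0.17 and -0.16). The mesenchymal list had a median of -0.17 at percentile 2.19, with members on both sides. LOX was 3.24-fold higher, while TGFB2 was 2.68-fold and THBS1 2.22-fold lower. The fatty acid list had a median of -0.18 at percentile 2.16. The desaturase gene SCD5 was 2.02-fold lower, under 2-fold with each of the 3 other scalings, and LPIN2, PLIN2 and LPIN1 were 1.83-fold, 1.81-fold and 1.77-fold higher.

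**Figure D3:**
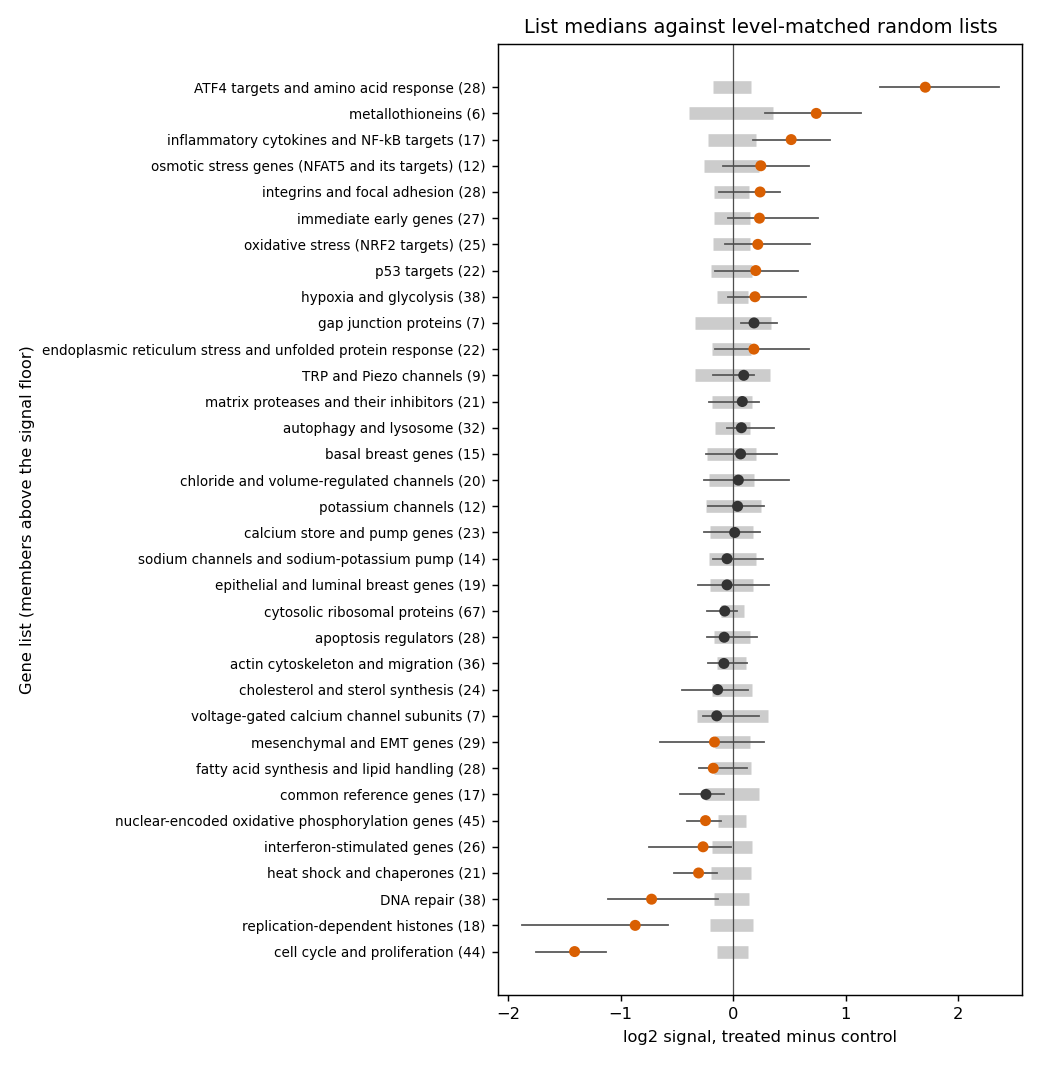
Median log2 treated minus control (x axis, points) of the 34 gene lists with at least 5 members above the floor (y axis), with quartiles as lines and the central 95% of 10000 level-matched random lists as grey bars; orange marks the 18 lists outside that range. The ATF4 list (1.71) and the cell cycle list (-1.41) lie furthest from their bars.

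Ion channel genes above the floor, listed because the saline had been exposed to an electric field, showed few differences as groups. No channel list stood apart, and 0 of 12 potassium channel, 0 of 14 sodium channel and pump, 0 of 9 TRP and Piezo and 0 of 7 voltage-gated calcium channel genes differed by 2-fold. Their medians were 0.04, -0.05, 0.09 and -0.15. Only members above the floor were counted, out of 40, 27, 23 and 23 genes listed, so many channel genes were not assessed. Of all genes above the floor 6.69% passed 2-fold, so counts of 0 in lists this small do not set channel genes apart. The members with the largest differences were KCNK5 (-0.67) and KCND1 (0.38), SCN9A (0.61) and ATP1B1 (-0.41), PKD2 (-0.36) and MCOLN2 (-0.33), and CACNB4 (-0.79) and CACNA1I (-0.37). Of 20 chloride and volume-regulated channel genes (median 0.05), CLIC4 was 2.57-fold higher and LRRC8D, a subunit of the volume-regulated anion channel, 1.98-fold higher. LRRC8D passed 2-fold under quantile normalization (1.02), median centring and the exon-level median (1.11). Of 23 calcium store and pump genes (median 0.01), the IP3 receptor gene ITPR1 (1.25) and the store-operated channel gene ORAI3 (1.11) were at least 2-fold higher, both named to complete the count.

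The 7 gap junction genes had a median of 0.19, with GJA1, the connexin 43 gene, at -0.78 and PANX2 at 0.62 (0.32 with the exon-level median). Only 2 aquaporin genes were above the floor, AQP3 at 0.00 and AQP5 at -0.03. Among 36 actin and migration genes (median -0.08), 0 passed 2-fold, and DIAPH3 (-0.94) and WASL (0.81) were furthest from 0.

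The remaining lists did not stand apart. The sterol synthesis list had a median of -0.14, and EBP (-1.26) and ACAT2 were its 2 members at least 2-fold lower. Apoptosis regulators had a median of -0.08, with APAF1 (-1.19) and CASP6 (-1.04) at least 2-fold lower. Autophagy and lysosome genes had a median of 0.07, with GABARAPL1 (1.40), MAP1LC3B (1.11) and WIPI1 (1.02) at least 2-fold higher. Epithelial genes had a median of -0.05, with ESRP1 (2.96), an epithelial splicing regulator gene, XBP1 and CLDN7 (1.13) at least 2-fold higher. Basal breast genes had a median of 0.07, with the keratin gene KRT81 (1.04) among those past 2-fold, and matrix proteases had a median of 0.08. Cytosolic ribosomal protein genes had a median of -0.07, with RPL37 (1.29) higher and RPLP0 (-1.03) lower. Except for XBP1, the genes of this paragraph were chosen after their values were seen.

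Common reference genes had a median of -0.24 at percentile 2.67, close to the limit of 2.5, and RPLP0 was the 1 of 17 past 2-fold. Markers of other cell types were mostly below the floor. Of the leukocyte markers, CD68 (0.29) and CD8A (0.26) were above it. Of the endothelial and blood markers, ESAM (-0.20), CLDN5 (-0.18) and HBA1 (0.01) were above it, and of the fibroblast markers COL1A1 (-0.17) was. These marker genes were likewise named to complete counts.

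Small RNA genes, which few probes measure, were counted apart. Of 306 above the floor, 10 were at least 2-fold higher and 6 at least 2-fold lower, with a median of -0.02. At exon level, 8105 of 176432 probe sets above the floor were at least 2-fold higher and 8629 at least 2-fold lower. Across 11341 genes with at least 3 probe sets, gene-level differences and the median exon-level differences had a Pearson r of 0.990 and a Spearman rho of 0.986. Of 765 genes past 2-fold, 765 had the same sign at exon level. The genes are not independent replicates, and both levels come from the same hybridisation. Their agreement is therefore no independent check of any difference.

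The authors' deposited table lists 1197 probe sets as lower in treated medium, with control over treated ratios of 2.00 to 18.7, and 869 as higher. These counts include probe sets at any signal. Of them, 659 (55.1%) in the authors' deposited list of lower probe sets and 327 (37.6%) in that of higher ones had no gene symbol.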

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

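The tests in this part were chosen after the patterns they bear on had been seen. Of the probe sets without a gene symbol that occur in both the gene-level and the exon-level table, 506 were at least 2-fold lower in treated medium, which drew attention because no gene-based comparison uses them. They are 42.3% of all 1197 lower probe sets, and 88 of the same kind were at least 2-fold higher.

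The first pattern is this excess of lower unnamed probe sets. A shift shared by all probe sets of these signal levels finds no support, since the median of the 5391 unnamed probe sets was -0.17 and the lowest median of 1000 level-matched draws of named ones was -0.023. It stays open what they measure: control, intronic or other probe sets that measure no named mRNA are candidate sources, and 0 of these probe sets have a symbol to decide it. If they are array controls, the 506 lower ones may say nothing about expression. No biological explanation was tested.

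The second pattern is the higher level of the ATF4 list. In the normalized values, the fitted trend of the difference on signal level reached at most 0.024 in size among the list's members. The list median was 1.71, so a trend left in these values does not account for it. A trend before RMA cannot be judged, since RMA forces the arrays to 1 distribution and leaves little of it. Endoplasmic reticulum stress with its chaperone arm stays open. Of 13 chaperones and folding enzymes 5 were above 0, and their median was -0.15 at percentile 11.8. DNAJB9 (2.01) was the 1 at least 2-fold higher, and 0 were lower by as much. The list of endoplasmic reticulum stress genes, which includes these 13, lay at percentile 98.7. ERN1 (3.36), HERPUD1 (1.62) and XBP1 (1.27) were higher, but they are not among the 13 chaperones and folding enzymes. Without ERN1 the endoplasmic reticulum stress list no longer stood apart. A shared ATF4 programme that reaches genes outside the ATF4 list may also account for the second pattern. The cytosolic aminoacyl-tRNA synthetases, none of them in the ATF4 list, had a median of 0.48 at percentile 100. Exposed saline and a difference between the 2 cultures other than the exposed saline cannot be told apart with 1 column of values per medium.

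The third pattern is the lower level of the cell cycle list. In the normalized values, the fitted trend of the difference on signal level reached at most 0.022 in size among its members. The list median was -1.41, so a trend left in these values does not account for it. As for the ATF4 list, a trend before RMA cannot be judged. Outside that list, 26 replication genes had a median of -1.13 and 24 mitosis genes a median of -1.55. The lower level was therefore not confined to genes of replication or to genes of mitosis. Loss of cells in 1 phase of the cycle only stays open, because signal averaged over all cells does not count cells per phase. Genes of both kinds can also fall together. An effect of exposed saline and a difference between the 2 cultures other than the exposed saline cannot be told apart with 1 column of values per medium.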

How the results depend on the processing

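The second set of random lists, leaving out ATF4-list genes and the identifier intervals behind the exon-level medians were chosen after seeing the data. No list that stood apart reversed under any alternative run, and 10 of the 18 stood apart under every alternative that left them at least 5 members: ATF4, cell cycle, histones, DNA repair, metallothioneins (too few members for the exon-level median), inflammatory, heat shock, hypoxia, immediate early and oxidative phosphorylation. Over these settings the ATF4 median ranged from 1.67 to 1.74 and the cell cycle median from -1.47 to -1.38. Among these 10 lists, medians moved by over 1.5 times from the main setting for inflammatory genes (range 0.17 to 0.65), metallothioneins (0.37 to 0.77) and histones (-0.96 to -0.50). The histone median of -0.50 covers only the members with at least 3 exon-level probe sets. The heat shock median ranged from -0.37 to -0.23. The other 8 lists lost their place at least once, and the cause was not tested. With a floor at the 75th percentile these were osmotic stress (0.28), NRF2 targets (0.15), p53 targets (0.20), interferon (-0.14), fatty acid (-0.17) and mesenchymal genes (-0.11). Without a floor they were endoplasmic reticulum stress (0.11), mesenchymal (-0.13) and integrin genes (0.045). With exon-level medians they were endoplasmic reticulum stress (0.11), p53 (0.17), fatty acid (-0.16) and mesenchymal genes (-0.17). Without the largest member they were endoplasmic reticulum stress (0.11), interferon (-0.14) and fatty acid genes (-0.17), and with the mean over clusters fatty acid genes (-0.18). The second set of random lists put the common reference genes at percentile 2.33 in place of 2.67, so that they stood apart (-0.24), as they also did under quantile normalization (-0.22), without a floor and with the mean over clusters. It changed no other list's place. Higher and lower genes numbered 196 and 265 with the floor at the 75th percentile, 1169 and 1203 at 1.5-fold and 113 and 117 at 3-fold. Exon-level probe sets numbered 22453 and 23668 without a floor, 3485 and 4113 with the higher floor, 22364 and 23443 at 1.5-fold, and 2303 and 2303 at 3-fold. Under quantile normalization there were 422 higher and 396 lower genes. No replicate could be left out. No paired analysis was possible because each group had 1 column and no test was run. Low signal limits the values of genes and probe sets under the floor. They enter where no floor was set, and also in the olfactory receptor genes, the unnamed probe sets and the authors' deposited counts.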

Other observations

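The lists in this part, and the values taken from them, were chosen after seeing the results. Among 20 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs in the cytosol, 7 were at least 2-fold higher and 0 were lower by as much. WARS (1.65), AARS (1.51) and GARS (1.40) had the highest differences, while QARS was at -0.56. The 17 mitochondrial synthetase genes had a median of -0.26 at percentile 2.45, close to the limit of 2.5, and 0 passed 2-fold.

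Of 20 amino acid transporter genes, 7 were at least 2-fold higher and the median was 0.62 at percentile 100, although 4 of the genes also belong to the ATF4 list. SLC6A9 (3.37), SLC1A4 (2.82) and SLC7A11 (1.47) had the highest differences, and the glutamate transporter gene SLC1A1 was at -1.19. Of 16 genes of G1 to S phase 12 were at least 2-fold lower, and of 25 G2 and mitosis genes 24 were at least 2-fold lower, but all of these genes belong to the cell cycle list. Outside it, 17 of 26 replication genes and 20 of 24 mitosis genes were at least 2-fold lower and 0 at least 2-fold higher. Of 5 EGF family ligand genes (median 0.19, percentile 85.4), AREG was at 1.77, EREG at 0.59 and NRG1 at -0.41.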
